A study of Homo sapiens with 12 samples.

How the data were processed

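RNA was sequenced from LN229, an established human glioblastoma cell line, in 12 libraries. The cells were grown to 80% confluence and then kept for 24 hours in RPMI with 10% dialyzed serum, which holds little glucose or acetate of its own. The medium held 1 mM glucose, 1 mM glucose with 5 mM acetate, or 10 mM glucose, and each of these 3 conditions had 4 replicates. RNA was extracted with Trizol and libraries were made by standard Illumina protocols. The strand setting, aligner and counting program are not given in the sources used here, and the build named there is hg19.

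The authors deposited raw counts for 34917 RefSeq transcripts per library, as whole numbers with no normalization. A read that overlaps several transcripts of a gene might be counted in each of them, which was not tested, so transcripts were not added up. For 20895 of the 22257 genes the authors had marked 1 transcript, which had the highest total count of its gene in 96.9% of cases. That transcript stood for its gene, and the transcript with the highest total stood for the 1362 genes with no mark. Reads shared between near-identical genes, such as HSPA1A and HSPA1B, or between ribosomal protein genes and their pseudogenes, could not be assigned from these counts.

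Total counts after this step ran from 24.4 M to 27.2 M per library (M, mega). Levels are given as CPM (counts per megacount). With 4 replicates per group the common biological coefficient of variation was 8.51%. Depth was not varied, so how far depth and the spread between libraries each set the precision was not tested.

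Genes were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling and the quasi-likelihood F test, fitting the 12 libraries together with 1 mean per group. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 14416 genes tested count as called. The 3 comparisons were 10 mM against 1 mM glucose, acetate against 1 mM glucose alone, and 10 mM glucose against acetate. The last is also the test of the difference between the other two. Log2 fold changes are the first group minus the second, each with a standard error (SE) taken from the F statistic, and CPM are scaled by TMM and given as mean ± SD. The replicates are not said to be separate cultures, so each p measures the spread between these samples, which may be technical.

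A set of 30 gene lists was written down before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of these lists, 28 had at least 5 tested members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. The camera p-values were adjusted by Benjamini-Hochberg over the 28 lists. Counts of called members are given over all genes and adjusted over the list alone. Neuron markers, with 3 of 8 members tested, and blood and endothelial markers, with 2 of 9, had too few members. The rule named the 6 genes with the highest and the 6 with the lowest fold change for glucose and for acetate, and 3 each way for the remaining difference. These had to be called, average at least 5 CPM and have groups that did not overlap. It also named the 3 called members with the smallest p in up to 8 called lists, and TXNIP, ARRDC4, SLC2A1, HK2, ACSS2, ACLY, FASN, HMGCS1, ASNS and HSPA5 throughout. Other members of the lists that the text names, such as DDIT3, IFIT1, CA9, VEGFA, IL6, CYR61 and MKI67, fall outside this rule and were chosen after their values were seen, so they do not stand for their lists.

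Alternatives were DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter at a mean of 5 CPM, a 1.5-fold minimum, only the 8 libraries compared, the replicate number as a block, and leaving out each library in turn. For lists, camera with an estimated correlation and fry, which tests a list against no change, were run with the main settings only. For the overlap of the comparisons the 1 mM controls were divided between them. After the libraries had been seen, 5 more were added: the transcript with the highest total for every gene, only marked transcripts, leaving out 2 libraries that stood apart, and removing each library's trend over transcript length and GC content by a spline with 5 degrees of freedom, with and without the block. The scaling alternatives were then also run for the lists, and library totals for the overlap. Lengths and GC came from GENCODE v29, matched by transcript accession for 20991 genes and by symbol for 725. No coordinates are given because that annotation is on another build than the counts.

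The procedure was tested on simulated data, 5 sets made by changing 200 genes in the acetate comparison. It recovered 52.8% of genes changed 1.25-fold, 97.2% at 1.5-fold and 100% at 2-fold, and 6.32% of its calls were false. The changed genes averaged at least 5 CPM at 1 mM glucose, and these sets held no length and GC trend. The recovery rates do not cover lower genes, and these rates do not cover data with such a trend. A list moved in each set was called in 5 of 5, and 0 other lists were called. Genes were simulated independently of each other, while estimated correlations within the real lists reached 0.896. The simulation therefore does not measure false list calls in the real data.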

Results

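Transcript counts were measured in LN229 glioblastoma cells after 24 hours in 1 mM glucose, in 1 mM glucose with 5 mM acetate, or in 10 mM glucose, with 4 libraries per condition. Total counts averaged 25.8 ± 0.616 M at 1 mM glucose, 26.9 ± 0.17 M with acetate and 25.6 ± 0.79 M at 10 mM glucose (SD, n = 4 each), so depth differed little between conditions. The 10 most abundant genes held 5.91 ± 0.187% of the counts at 1 mM glucose, 5.86 ± 0.104% with acetate and 3.62 ± 0.102% at 10 mM glucose (SD, n = 4). HSPA5, the chaperone BiP of the endoplasmic reticulum (ER), by itself held 1.2% to 1.38% of the counts in the 8 libraries at 1 mM glucose and 0.123% to 0.126% at 10 mM. A group with acetate at 10 mM glucose is not analysed here. The comparisons ask which transcripts depend on glucose supply, and how far acetate, a carbon source that ACSS2 can turn into acetyl-CoA, changes them when glucose is low.

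Glucose supply was the main difference between libraries. The first principal component held 74.8% of the variance and ran from −36.8 to −31.2 at 1 mM glucose, from −27.3 to −16.1 with acetate and from 54.2 to 56.8 at 10 mM glucose. The second held 8.35% and set apart 1 mM replicate 3 (31.4) and acetate replicate 1 (14.9). These libraries also had the strongest relation with transcript length. Across genes, which are not independent replicates, the Spearman correlation of a library's deviation from the mean with transcript length was −0.559 and −0.542 in them and −0.211 to 0.27 in the other 10 libraries.

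**Figure D1:**
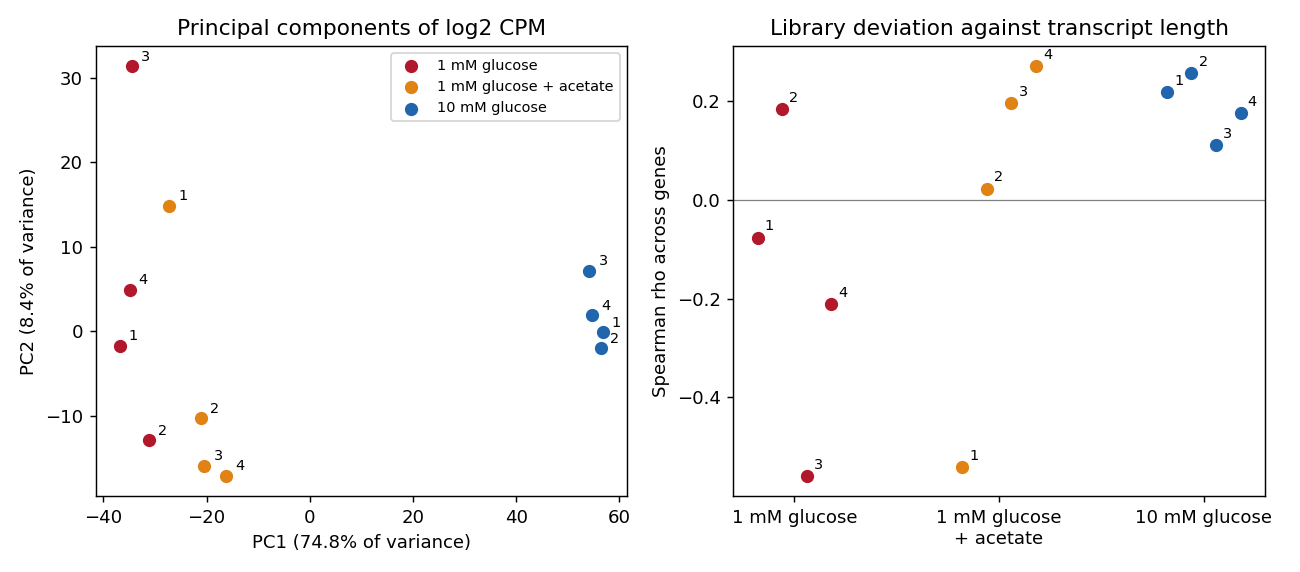
Left, the first and second principal components of log2 CPM (no unit) for the 12 libraries, colored by condition; right, Spearman's rho across genes between each library's deviation and transcript length. The 10 mM libraries lie apart on the first component, and 1 mM replicate 3 and acetate replicate 1 have the lowest rho, −0.559 and −0.542.

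At 10 mM glucose the cells had much lower levels of ER chaperone and unfolded protein response transcripts than at 1 mM, the single list called by camera with a preset and with an estimated correlation. With the preset correlation alone the amino acid response list was also lower and the mitosis and DNA replication lists higher. HSPA5 averaged 13042 ± 489 CPM at 1 mM and 1183 ± 12.0 CPM at 10 mM, a log2 fold change of −3.46 ± 0.05 (SD, n = 4, and SE). ASNS, the asparagine synthetase that ATF4 induces, went from 637 ± 16.2 to 139 ± 4.9 CPM, a log2 fold change of −2.19 ± 0.06 (SE). TXNIP, an inhibitor of glucose uptake under control of the glucose sensor MondoA, rose from 6.63 ± 0.652 to 121 ± 4.54 CPM, or 18.3-fold. KIF20A, a kinesin needed for cell division, rose from 75.7 ± 6.4 to 311 ± 10.3 CPM, or 4.11-fold. These changes had edgeR adjusted p = 4.2e-15 for HSPA5, 3.2e-13 for ASNS, 9.4e-15 for TXNIP and 2.4e-12 for KIF20A.

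Among called genes that averaged at least 5 CPM and whose groups did not overlap, the 6 largest increases were TXNIP (log2 fold change 4.19 ± 0.08, SE), the transcription factor ATOH8 (3.14 ± 0.13), the Hedgehog receptor PTCH1 (3.02 ± 0.13), the receptor tyrosine kinase PDGFRA (2.94 ± 0.10), TRIL (2.89 ± 0.14) and MYCN (2.76 ± 0.13). PDGFRA averaged 5.48 ± 0.736 CPM at 1 mM and 42.1 ± 2.42 CPM at 10 mM (SD, n = 4). The 6 largest decreases were IL1RL1, the interleukin-33 receptor (−7.32 ± 0.19), KLHDC7B (−6.64 ± 0.23), SPRR2D (−6.23 ± 0.20), the stress-induced chaperone HSPA6 (−6.13 ± 0.26), the heme oxygenase HMOX1 (−5.80 ± 0.17) and the stress cytokine GDF15 (−5.59 ± 0.14). IL1RL1 fell from 103 ± 18.1 to 0.634 ± 0.117 CPM and HMOX1 from 571 ± 113 to 10.2 ± 0.924 CPM. SPRR2D and HSPA6 have close relatives, and reads shared with those cannot be told from their own.

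Stress and amino acid lists were lower at 10 mM. Every one of the 24 tested ATF4 and amino acid response genes fell, with a median log2 fold change of −1.82 (camera adjusted p = 8.1e-16, and adjusted p = 0.0571 with an estimated correlation). Among them were the cell death factor DDIT3 (−4.48), the eIF2-alpha phosphatase subunit PPP1R15A (−3.80), the secreted factor STC2 (−3.79) and the mTORC1 regulator SESN2 (−3.61). The 20 ER chaperone and unfolded protein response genes all fell, with a median of −2.01, and this call held with an estimated correlation (camera adjusted p = 8.7e-14, and adjusted p = 0.0352 with an estimated correlation). HERPUD1, which serves degradation of ER proteins, changed by −4.08 ± 0.07 and the co-chaperone DNAJB9 by −3.59 ± 0.07 (SE). Of 14 NRF2 antioxidant genes 11 fell and 2 rose, with a median of −1.37 (camera adjusted p = 1.6e-04, and adjusted p = 0.137 with an estimated correlation). In the hexosamine and O-GlcNAc list 7 of 8 genes fell and 1 rose, with a median of −0.61 (camera adjusted p = 0.0046, and adjusted p = 0.269 with an estimated correlation). Its rate-limiting enzyme GFPT1 fell by 2.21 and UAP1 by 2.01 on the log2 scale. In the autophagy and lysosome list 11 of 19 genes fell and 2 rose (median −0.21, camera adjusted p = 0.0058, and adjusted p = 0.407 with an estimated correlation), among them the receptor SQSTM1 (−2.32) and MAP1LC3B (−2.16).

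Signalling and translation lists were lower as well. Of 14 immediate early genes 13 fell, including FOSB (−3.98 ± 0.11, SE), the phosphatase DUSP1 (−3.06 ± 0.09) and KLF4 (−2.26 ± 0.07), while EGR3 rose by 0.41 (median −0.93, camera adjusted p = 2.9e-05, and adjusted p = 0.153 with an estimated correlation). Of 13 inflammatory and NF-kB genes 10 fell, including the cytokines IL6 (−3.49) and IL1A (−3.19) and the cyclooxygenase PTGS2 (−3.64), and 1 rose (median −1.45, camera adjusted p = 6.5e-04, and adjusted p = 0.198 with an estimated correlation). Of 19 ribosome biogenesis and MYC-linked genes 16 fell (median −0.37, camera adjusted p = 4.5e-05, and adjusted p = 0.153 with an estimated correlation). MYC itself went from 125 ± 8.73 to 19.8 ± 1.09 CPM (SD, n = 4), and ODC1, the first enzyme of polyamine synthesis, changed by −1.02. The 24 cytosolic ribosomal protein genes all fell, with a median of −0.70 (camera adjusted p = 8.9e-07, and adjusted p = 0.441 with an estimated correlation). RPL3 changed by −0.99 ± 0.07, RPL4 by −0.77 ± 0.07 and RPL5 by −0.79 ± 0.08 (SE), and the many pseudogenes of this family leave their absolute levels uncertain. After each library's length and GC trend was removed the median was −0.48.

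Cell-cycle lists were higher at 10 mM. The 29 mitosis genes all rose, with a median of 1.24 (camera adjusted p = 1.1e-13, and adjusted p = 0.137 with an estimated correlation). The proliferation marker MKI67 rose by 2.04, the topoisomerase TOP2A by 1.67, the kinase AURKA by 1.56 ± 0.06 and DLGAP5 by 1.74 ± 0.07 on the log2 scale (SE). In the DNA replication list 32 of 34 genes rose, with a median of 0.82 (camera adjusted p = 1.2e-10, and adjusted p = 0.153 with an estimated correlation). ORC1, of the origin recognition complex, rose by 1.33 ± 0.06, and GINS1 and GINS4, of the replicative helicase, by 1.35 ± 0.06 and 1.19 ± 0.06 (SE). The helicase loader CDC6 fell, by 0.98 on the log2 scale. All 13 homologous recombination and mismatch repair genes rose, among them RAD54L (0.90), BLM (0.82) and FANCD2 (0.80), with a median of 0.66 (camera adjusted p = 1.0e-05, and adjusted p = 0.206 with an estimated correlation). Of 14 interferon response genes 8 rose and 2 fell (median 0.31, camera adjusted p = 0.0301, and adjusted p = 0.224 with an estimated correlation), with IFIT1 at 2.96.

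Metabolic lists moved both ways. In the glycolysis list 12 of 21 genes rose and 6 fell (camera adjusted p = 0.306). Lactate dehydrogenase LDHA rose by 1.36, while the glucose transporters SLC2A1 and SLC2A3 changed by −0.93 and −1.64 and hexokinase HK2 by −1.16 on the log2 scale. The acetyl-CoA list had 11 of 18 genes higher and 2 lower (median 0.33, camera adjusted p = 0.052), including the acetyl-CoA synthetase ACSS2 (0.32), the citrate lyase ACLY (0.41) and the pyruvate dehydrogenase kinase PDK3 (1.24). Fatty acid synthesis had 8 of 16 higher and 5 lower (camera adjusted p = 0.402), with the synthase FASN at 0.66 ± 0.13 (SE), and cholesterol synthesis 11 of 23 higher and 6 lower (camera adjusted p = 0.328), with HMGCS1 at 0.34. Of the 6 MondoA and ChREBP genes TXNIP, ARRDC4 (1.53) and MLXIP (0.29) rose and 3 fell (camera adjusted p = 0.694), and the median of −0.03 and the mean of 0.80 differ in sign. The tricarboxylic acid (TCA) cycle and respiratory chain list had 12 of 25 genes lower and 2 higher (camera adjusted p = 0.169).

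The other lists were not called for glucose. Histone genes had 10 of 14 higher and 2 lower, and extracellular matrix and TGF-beta/YAP genes 5 of 18 higher and 11 lower, including the YAP target CYR61 (−3.05), each with camera adjusted p = 0.0974. Histone acetyltransferases had 5 of 12 higher and 3 lower, and deacetylases and sirtuins 4 of 18 higher and 6 lower with HDAC4 higher and HDAC9 at −1.67 (median 0.03, mean −0.05). Hypoxia genes had 8 of 16 higher and 7 lower, with the carbonic anhydrase CA9 at 2.95 and VEGFA at −2.63 (median 0.29, mean −0.04). The p53 list had 3 of 14 higher and 6 lower, the FOXO list 2 of 12 higher and 6 lower, and the pentose phosphate list 3 of 11 higher and 5 lower. Astrocyte and glial progenitor markers had 4 of 7 higher and 2 lower, with the stem-cell factor SOX2 at 2.40 and OLIG2 at −1.56. Neuron markers and blood and endothelial markers were too few to test, and the highest group mean of a member was 114 CPM for SYT1 and 65.0 CPM for CD68.

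In total 9725 of 14416 tested genes (67.5%) were called by edgeR, 4854 higher and 4871 lower at 10 mM, and 4547 of them differed at least 1.5-fold. In 8861 genes (61.5%) the libraries of the groups did not overlap, against 2.86% by chance. With library totals in place of TMM the median log2 fold change moved by 0.14, and 63.3% of calls were higher in place of 49.9%, so the split between higher and lower depends on the scaling. Adjusted over the list alone the counts above were the same except for DNA replication (33 higher, 1 lower), interferon (9 and 2), TCA cycle (1 and 7), hypoxia (9 and 7) and extracellular matrix (6 and 11).

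**Figure D2:**
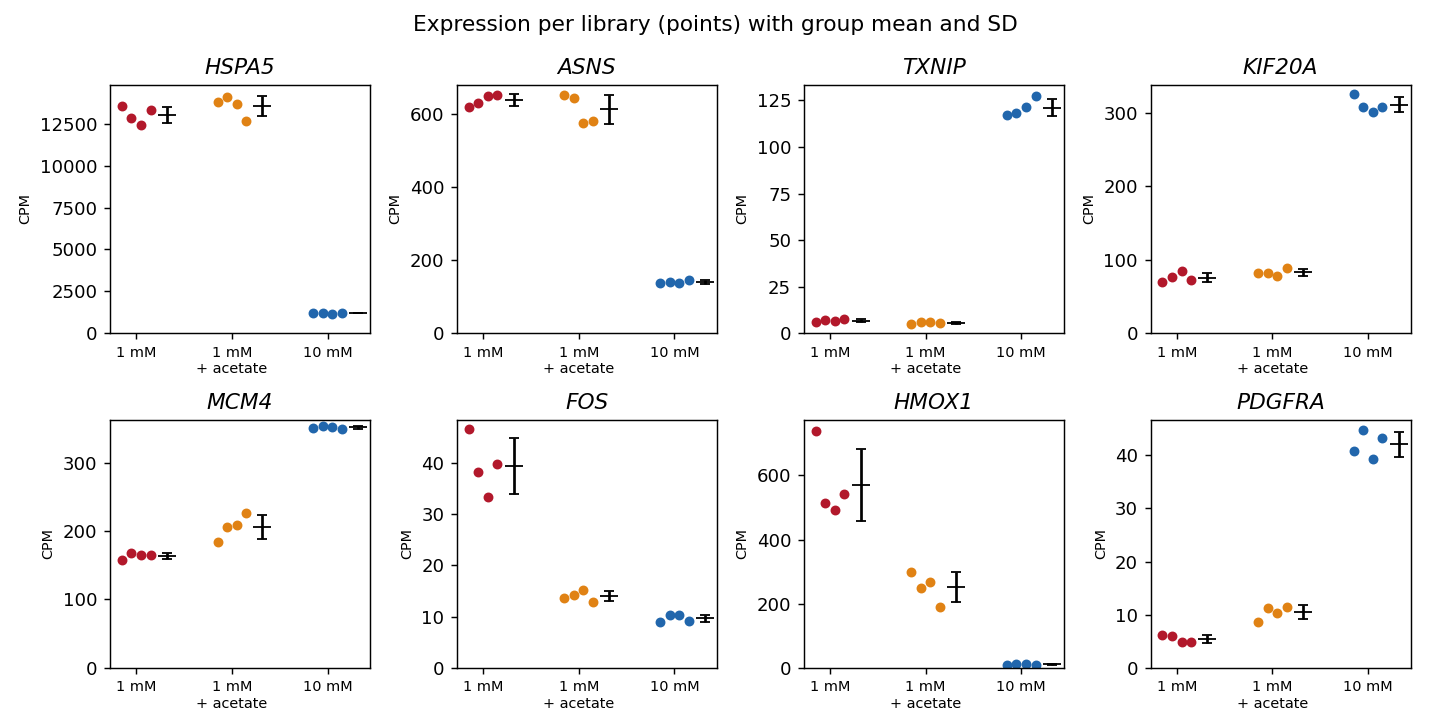
CPM scaled by TMM (vertical axes, from 0) of 8 genes in each library by condition, with points for the 4 libraries and lines for the mean ± SD. HSPA5 and ASNS have means of 13575 and 612 CPM with acetate, near those at 1 mM glucose alone, FOS and HMOX1 are lower with acetate, and TXNIP and KIF20A rise at 10 mM.

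NRF2 antioxidant transcripts were lower with acetate at 1 mM glucose, the single list called by camera with a preset and with an estimated correlation. The estimated correlation gave camera adjusted p = 0.0424 and was run with the main settings only. Whether that call holds with a library left out was not tested. With the preset correlation alone 12 more lists were called, among them immediate early genes and ATF4 and amino acid response genes (lower) and DNA replication genes (slightly higher). The ER chaperone HSPA5 and the ATF4 target ASNS did not pass the test. FOS, an early transcription factor of the growth response, fell from 39.5 ± 5.45 to 14.0 ± 0.939 CPM, or 2.82-fold (SD, n = 4, edgeR adjusted p = 7.7e-07). HMOX1, an NRF2 target, fell from 571 ± 113 to 251 ± 46.2 CPM. MCM4, a subunit of the replicative helicase, rose from 164 ± 4.23 to 206 ± 17.7 CPM, a log2 fold change of 0.33 ± 0.06 (SE). HSPA5 had 13042 ± 489 CPM without and 13575 ± 610 CPM with acetate, a log2 fold change of 0.06 ± 0.05 (edgeR adjusted p = 0.483).

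By the same limits the 6 largest increases with acetate were the IGF-binding protein IGFBP5 (log2 fold change 1.12 ± 0.15, SE), the semaphorin SEMA6B (1.11 ± 0.08), the protease inhibitor SERPINA5 (1.09 ± 0.08), PDGFRA (0.93 ± 0.11), the adhesion protein CNTN1 (0.86 ± 0.13) and the creatine kinase CKB (0.83 ± 0.11). IGFBP5 averaged 17.7 ± 3.33 CPM without and 38.7 ± 8.22 CPM with acetate (SD, n = 4). The 6 largest decreases were HSPA6 (−1.75 ± 0.20), FOS (−1.50 ± 0.09), SPRR2D (−1.40 ± 0.13), the differentiation inhibitor ID2 (−1.40 ± 0.08), and the heat shock proteins HSPA1A (−1.39 ± 0.15) and HSPA1B (−1.34 ± 0.14). HSPA1A averaged 781 ± 197 CPM without and 299 ± 53.2 CPM with acetate, and reads shared with its near-identical neighbour HSPA1B, if any, were not told apart.

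Immediate early genes had the smallest p by camera with the preset correlation, and NRF2 genes with an estimated one. Of 14 members 11 fell (11 adjusted over the list alone), including DUSP1 (−1.15 ± 0.08, SE), FOSB (−1.02 ± 0.08) and EGR1 (−0.50), with a median of −0.40 (camera adjusted p = 1.4e-09, and adjusted p = 0.0939 with an estimated correlation). Of 14 NRF2 antioxidant genes 10 fell (12 adjusted over the list alone), with a median of −0.39, and this call held with an estimated correlation (camera adjusted p = 2.0e-09, and adjusted p = 0.0424 with an estimated correlation). The sulfiredoxin SRXN1 changed by −0.68 ± 0.05, OSGIN1 by −1.05 ± 0.08, HMOX1 by −1.18 ± 0.14 and the glutathione synthesis subunit GCLM by −0.73. Of 24 ATF4 genes 13 fell (15 adjusted over the list alone), with a median of −0.19 (camera adjusted p = 5.3e-09, and adjusted p = 0.197 with an estimated correlation). ATF3 (−0.74 ± 0.07), SESN2 (−0.56 ± 0.05) and PPP1R15A (−0.47 ± 0.06) were among these, while DDIT3 had 0.02 and ASNS −0.06 (edgeR adjusted p = 0.522 for ASNS). The autophagy and lysosome list had 6 of 19 genes lower (8 adjusted over the list alone), GABARAPL1 (−0.64), SQSTM1 (−0.56) and MAP1LC3B (−0.50) among them, with a median of −0.16 (camera adjusted p = 3.2e-05, and adjusted p = 0.255 with an estimated correlation). The hexosamine list had 3 of 8 lower (4 adjusted over the list alone), namely GFPT2 (−0.73), UAP1 (−0.34) and NAGK (−0.30), with a median of −0.20 (camera adjusted p = 0.0043, and adjusted p = 0.302 with an estimated correlation). The edgeR call of NAGK ended without 1 mM replicate 3 or 4 (0.0505, 0.0515) or acetate replicate 2, 3 or 4 (0.053, 0.0837, 0.0885). It also ended with library totals (0.0514) and with only the 8 libraries compared (0.0788), over its alternatives 0.0012 to 0.0885.

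Part of the DNA replication and repair lists was higher with acetate, and both list calls were lost with an estimated correlation. In the DNA replication list 15 of 34 genes rose (19 adjusted over the list alone), among them MCM10 (0.48 ± 0.07, SE) and MCM3 (0.33 ± 0.06), and CDC6 fell by 0.17 on the log2 scale, with a list median of 0.20 (camera adjusted p = 5.3e-09, and adjusted p = 0.255 with an estimated correlation). In the recombination and repair list 6 of 13 rose (12 adjusted over the list alone), FANCD2 (0.27 ± 0.06), MSH6 (0.24 ± 0.06) and BRIP1 (0.32 ± 0.09) among them, with a median of 0.19 (camera adjusted p = 1.4e-05, and adjusted p = 0.262 with an estimated correlation). The edgeR call of BRIP1 ended without 1 mM replicate 1 or 4 (0.0864, 0.06) or acetate replicate 2, 3 or 4 (0.056, 0.0536, 0.0888). It also ended with only the 8 libraries compared (0.0724), over its alternatives 0.0031 to 0.0888. That of MSH6 ended with the length and GC trend removed and the replicate block (0.0564, over its alternatives 0.002 to 0.0564). Of 29 mitosis genes edgeR called 0 (0 adjusted over the list alone), with a median of 0.02 (camera adjusted p = 0.999). At an unadjusted p under 0.05 edgeR had 1 higher and 3 lower, DESeq2 called 1 higher and 1 lower, and limma-voom called 0.

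A further 6 lists had camera adjusted p between 0.0344 and 0.0424, and each of their calls was lost when some single library was left out. ER chaperone genes had 5 of 20 lower (5 adjusted over the list alone; median −0.08; adjusted p = 0.376 with an estimated correlation), XBP1 (−0.31), CRELD2 (−0.34) and DNAJB9 (−0.27) among them, and camera adjusted p = 0.107 without acetate replicate 4. The edgeR call of CRELD2 ended without 1 mM replicate 1 (0.0624) or acetate replicate 2, 3 or 4 (0.0542, 0.052, 0.0693). It also ended with only the 8 libraries compared (0.0734), over its alternatives 1.8e-04 to 0.0734. The p53 list had 4 of 14 lower (7 adjusted over the list alone; median −0.19; adjusted p = 0.255 with an estimated correlation), including the cell-cycle inhibitor CDKN1A (−0.50), and camera adjusted p = 0.0719 without 1 mM replicate 2 and 0.0573 without acetate replicate 4. Cholesterol genes had 4 of 23 lower (5 adjusted over the list alone; median −0.07; adjusted p = 0.255 with an estimated correlation), including INSIG1 (−0.51), SQLE (−0.19) and LSS (−0.16), and camera adjusted p = 0.179 without 1 mM replicate 3 and 0.0936 without acetate replicate 3. The inflammatory list had 6 of 13 higher and 2 lower (7 and 2 adjusted over the list alone; median 0.31; adjusted p = 0.454 with an estimated correlation), with IL1B at 0.68 and PTGS2 at −0.56. Its camera adjusted p was 0.0565 and 0.127 without 1 mM replicates 1 and 2, and 0.129 and 0.069 without acetate replicates 1 and 3. The FOXO list had 4 of 12 lower (4 adjusted over the list alone; median −0.11; adjusted p = 0.365 with an estimated correlation), and camera adjusted p of 0.0602 and 0.105 without 1 mM replicates 1 and 2 and 0.129 and 0.0523 without acetate replicates 1 and 2. Ribosomal protein genes had a median of −0.11 with 0 of 24 called by edgeR (0 adjusted over the list alone; adjusted p = 0.762 with an estimated correlation), and camera adjusted p was 0.564 without 1 mM replicate 3, and 0.192 and 0.255 without acetate replicates 3 and 4. DESeq2 and limma-voom also called 0 of these, and edgeR had 0 at an unadjusted p under 0.05.

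Genes of acetate use and lipid synthesis changed little. ACSS2, which activates acetate, fell by 0.35 on the log2 scale (edgeR adjusted p = 5.0e-04), from 44.3 ± 1.74 to 34.8 ± 1.29 CPM (SD, n = 4). ACLY (0.04), FASN (0.05) and HMGCS1 (−0.18) had edgeR adjusted p of 0.688, 0.842 and 0.101. FASN passed without acetate replicate 1 (0.049) or the pair of libraries set apart by transcript length (0.0398), over its alternatives 0.0398 to 0.952. HMGCS1 passed without 1 mM replicate 3 (0.0362), and without that pair (0.0295). It also passed with the length and GC trend removed (0.0025, or 0.002 with the block), over its alternatives 0.002 to 0.269. SLC2A1 changed by −0.36 ± 0.06 and HK2 by −0.32 ± 0.08 (SE), and ARRDC4 had −0.08 (edgeR adjusted p = 0.732). The edgeR call of HK2 ended without 1 mM replicate 1 (0.0594) and with only the 8 libraries compared (0.0756), over its alternatives 7.6e-06 to 0.0756. TXNIP had −0.27 ± 0.08 with edgeR adjusted p = 0.0495, and this call ended without 1 mM replicate 2 or 4 (0.0822, 0.151) or acetate replicate 1, 2, 3 or 4 (0.0903, 0.082, 0.0534, 0.11). In edgeR it also ended with library totals (0.084), no filter (0.07), without the pair (0.0725) and with only the 8 libraries compared (0.155). By limma-voom TXNIP had adjusted p = 0.0769. The lists of acetyl-CoA production (2 of 18 higher, 1 lower), fatty acid synthesis (1 of 16 lower), glycolysis (2 of 21 higher, 6 lower), histone genes (1 of 14 higher, 2 lower), MondoA and ChREBP genes (2 of 6 lower), pentose phosphate (2 of 11 lower), ribosome biogenesis (2 of 19 lower), interferon (2 of 14 higher, 1 lower), hypoxia (2 of 16 higher, 2 lower), extracellular matrix (1 of 18 higher, 1 lower), astrocyte markers (2 of 7 higher, 2 lower) and histone acetyltransferases (1 of 12 higher) had camera adjusted p from 0.0773 to 0.999. Adjusted over the list alone the counts differed for glycolysis (7 lower), histone genes (4 lower), interferon (3 higher, 2 lower), hypoxia (3 higher, 6 lower) and pentose phosphate (3 lower). EdgeR called 0 of 25 TCA cycle genes and 0 of 18 deacetylases and sirtuins, also adjusted over the list alone, with camera adjusted p of 0.318 and 0.776. At an unadjusted p under 0.05 there were 2 TCA cycle genes lower, and 1 deacetylase higher and 1 lower, while DESeq2 called 1 lower in each list and limma-voom 0 and 1. In the fatty acid list the single call was not kept when adjusted over the list alone, which left 0 called by edgeR, against 5 higher and 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2 and by limma-voom. The camera direction was up against a negative median for acetyl-CoA (−0.01) and histone acetyltransferases (−0.01), up with a median of 0.04 and a mean of −0.01 for extracellular matrix, and down with a median of 0.12 for astrocyte markers.

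By edgeR 1980 of 14416 genes (13.7%) were called for acetate, 958 higher and 1022 lower, 380 of them at least 1.5-fold, and in 2242 genes (15.6%) the groups did not overlap. The count fell to 1294 without 1 mM replicate 1, 1278 without 1 mM replicate 4, 1318 without acetate replicate 3, 1196 without acetate replicate 4 and 1056 when only the 8 libraries compared were fitted, and it was 3728 without the pair of libraries set apart by transcript length and 3988 after the length and GC trend was removed. With library totals the median log2 fold change moved by 0.04, and 65.2% of calls were higher in place of 48.4%.

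**Figure D3:**
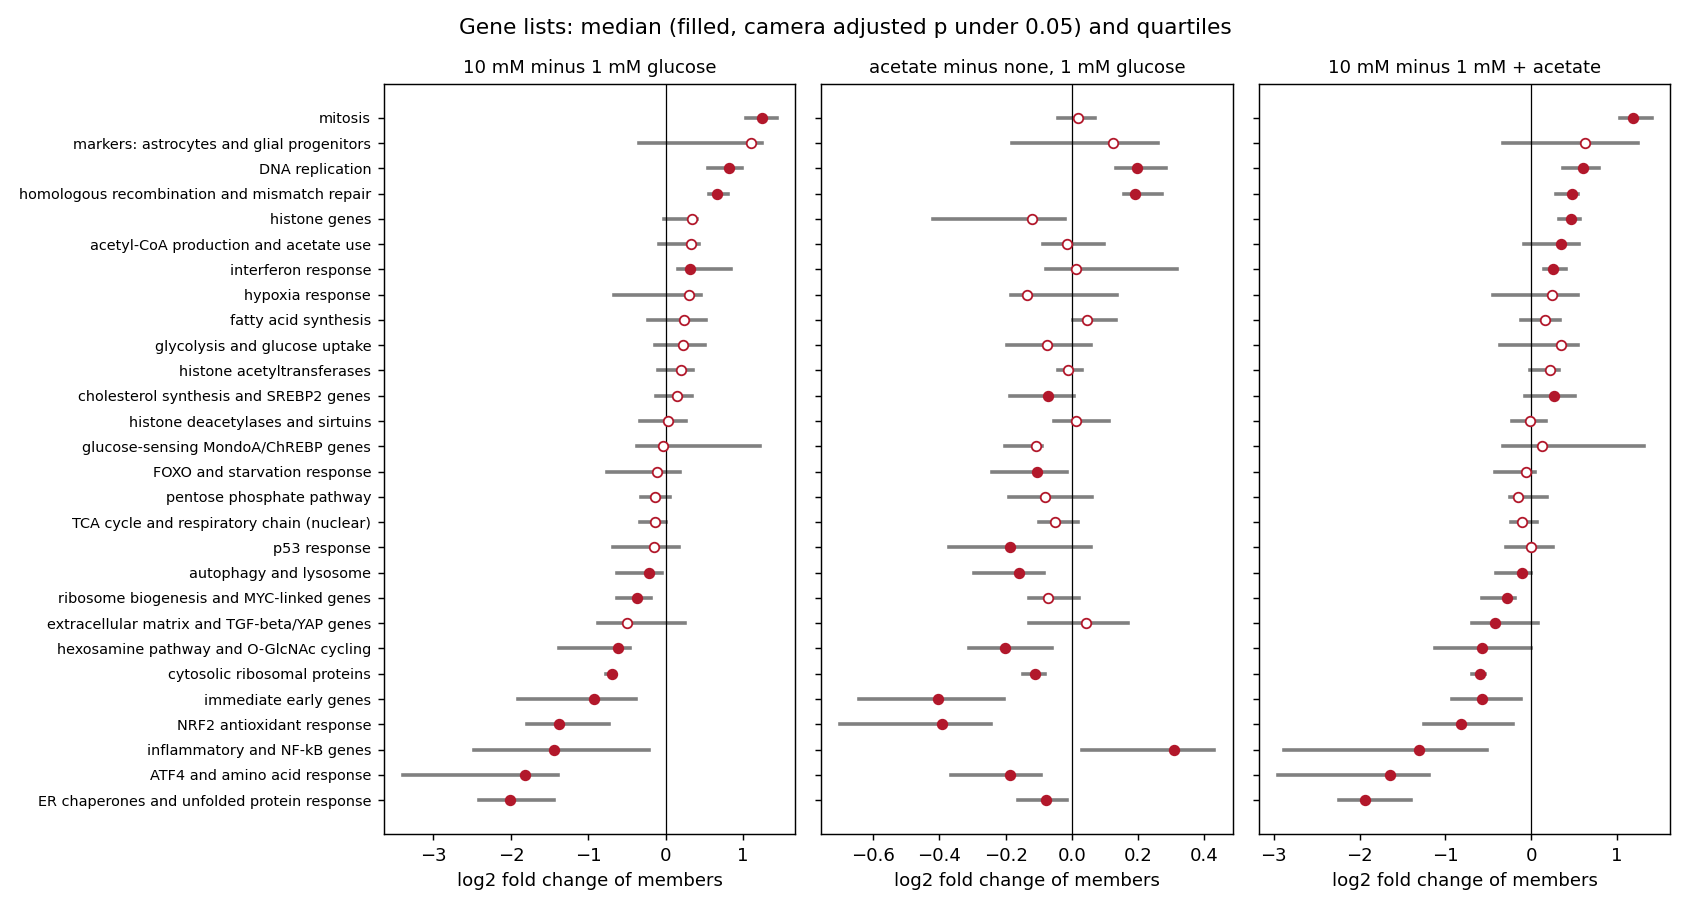
Median log2 fold change (point, filled where the camera adjusted p was under 0.05) and quartiles (line) of the members of 28 gene lists for 10 mM against 1 mM glucose, acetate against 1 mM glucose, and 10 mM glucose against acetate; the horizontal scales differ between panels. Mitosis has medians of 1.24, 0.02 and 1.19, and ER chaperones of −2.01, −0.08 and −1.94.

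Most of the glucose-dependent difference remained with acetate present. TXNIP was 22.0-fold higher at 10 mM glucose than with acetate (5.51 ± 0.437 and 121 ± 4.54 CPM, SD, n = 4), and HSPA5 was 11.5-fold lower (log2 fold change −3.52 ± 0.06, SE, edgeR adjusted p = 8.1e-15). By the same limits the largest other increases were RGMA, a repulsive guidance protein (2.73 ± 0.10), and PTCH1 (2.55 ± 0.13), and the largest decreases IL1RL1 (−6.70 ± 0.19), KLHDC7B (−6.02 ± 0.24) and GDF15 (−5.28 ± 0.14). Since the shared 1 mM group drops out, this contrast tests whether the glucose and acetate effects differ.

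ATF4 and ER lists were lower at 10 mM glucose than with acetate, and mitosis and replication lists higher. The 24 ATF4 genes were all lower (median −1.65, camera adjusted p = 8.6e-17), as were the 20 ER genes (median −1.94, camera adjusted p = 4.1e-15), and both calls held with an estimated correlation (camera adjusted p = 0.0478 and 0.0268). STC2 differed by −3.61, PPP1R15A by −3.34, SESN2 by −3.05, ASNS by −2.14, HERPUD1 by −4.09 and DNAJB9 by −3.32 (SE 0.05 to 0.07). The 29 mitosis genes were all higher (median 1.19, camera adjusted p = 1.5e-15, and adjusted p = 0.104 with an estimated correlation), with KIF20A at 1.91, AURKA at 1.67 and DLGAP5 at 1.71. Of 34 DNA replication genes 30 were higher, including ORC1 (1.07) and GINS1 (1.03), and CDC6 was lower by −0.81 (median 0.60, camera adjusted p = 3.4e-09, and adjusted p = 0.204 with an estimated correlation). The 13 recombination and repair genes were all higher, with BLM at 0.67, RAD54L at 0.68 and FANCI at 0.49 (median 0.47, camera adjusted p = 8.3e-05, and adjusted p = 0.244 with an estimated correlation). Histone genes were higher in 10 of 14 (median 0.46, camera adjusted p = 0.0039, and adjusted p = 0.418 with an estimated correlation), and interferon genes in 9 of 14 with 1 lower (camera adjusted p = 0.0397, and adjusted p = 0.244 with an estimated correlation).

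Ribosomal protein genes were lower in 23 of 24 (median −0.59, camera adjusted p = 2.1e-06, and adjusted p = 0.421 with an estimated correlation), RPL3 by −0.91, RPL4 by −0.67 and RPL5 by −0.75. Inflammatory genes were lower in 11 of 13, with IL1A at −3.50, IL8 at −2.88 and PTGS2 at −3.08 (median −1.31, camera adjusted p = 7.8e-06, and adjusted p = 0.157 with an estimated correlation). Ribosome biogenesis genes were lower in 16 of 19, with MYC at −2.25, ODC1 at −0.79 and GNL3, a nucleolar GTPase, at −0.61 (camera adjusted p = 3.9e-05, and adjusted p = 0.175 with an estimated correlation). Immediate early genes were lower in 10 of 14 and higher in 1 (camera adjusted p = 0.0016, and adjusted p = 0.244 with an estimated correlation), and NRF2 genes lower in 10 of 14 and higher in 2 (camera adjusted p = 0.0032, and adjusted p = 0.195 with an estimated correlation). The hexosamine list had 5 of 8 lower and 2 higher (camera adjusted p = 0.0423, and adjusted p = 0.419 with an estimated correlation).

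The acetate-activating enzyme ACSS2 and the lipid synthesis genes ACLY, FASN and HMGCS1 were higher at 10 mM glucose than with acetate, while their lists moved both ways. ACSS2 differed by 0.67 ± 0.05, ACLY by 0.37 ± 0.06, FASN by 0.61 ± 0.13 and HMGCS1 by 0.52 ± 0.07 (SE), ARRDC4 was higher by 1.61, and SLC2A1 and HK2 had −0.57 and −0.84. The acetyl-CoA list had 9 of 18 higher and 2 lower (camera adjusted p = 0.0423, and adjusted p = 0.175 with an estimated correlation), and it lost its call without acetate replicate 4 (camera adjusted p = 0.0547). The cholesterol list had 12 of 23 higher and 6 lower (camera adjusted p = 0.0447, and adjusted p = 0.23 with an estimated correlation), with adjusted p of 0.0501, 0.0635 and 0.0547 by camera without acetate replicate 2, 3 or 4 and 0.0518 without 10 mM replicate 3. The autophagy list had 9 of 19 lower and 3 higher (camera adjusted p = 0.0423, and adjusted p = 0.482 with an estimated correlation), and 0.058 without acetate replicate 1. Extracellular matrix genes had 11 of 18 lower and 3 higher (camera adjusted p = 0.0423, and adjusted p = 0.418 with an estimated correlation), and 0.0601 and 0.058 without acetate replicates 3 and 4. The lists of fatty acid synthesis (7 of 16 higher, 4 lower), glycolysis (13 of 21 higher, 7 lower), TCA cycle (2 of 25 higher, 8 lower), MondoA and ChREBP genes (3 of 6 higher, 2 lower), hypoxia (8 of 16 higher, 7 lower), p53 (5 of 14 higher, 5 lower), FOXO (2 of 12 higher, 5 lower), pentose phosphate (3 of 11 higher, 5 lower), histone acetyltransferases (4 of 12 higher, 3 lower), deacetylases (4 of 18 higher, 6 lower) and astrocyte markers (4 of 7 higher, 2 lower) were not called.

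In this comparison 9049 genes (62.8%) were called by edgeR, 4471 higher and 4578 lower, 3672 of them at least 1.5-fold, and in 8787 (61.0%) the groups did not overlap. With library totals the median log2 fold change moved by 0.10, and 60.8% of calls were higher in place of 49.4%. Adjusted over the list alone the counts differed for ribosomal proteins (24 lower), inflammatory genes (12 lower), ribosome biogenesis (17 lower), acetyl-CoA (3 lower), cholesterol (13 higher) and MondoA genes (3 lower).

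Acetate moved glucose-dependent genes mostly in the direction of glucose, by a fraction of its effect. Of 1708 genes called in both comparisons 1562 (91.5%) changed the same way, 766 higher and 796 lower in both, and 146 the opposite way. Genes are not independent replicates, so no interval is given for this share. PDGFRA rose by 0.93 with acetate and by 2.94 with glucose, and HMOX1 had −1.18 with acetate and −5.80 with glucose. ACSS2 was among the opposite genes, with −0.35 for acetate and 0.32 for glucose. Some lists did not follow glucose. The inflammatory list had a median of −1.45 for glucose and 0.31 for acetate, called both ways by camera with the preset correlation alone. The 29 mitosis genes were all higher for glucose, and edgeR called 0 of them for acetate. Of the 4547 genes that glucose changed at least 1.5-fold, 1065 (23.4%) were called in the same direction with acetate and 42 in the opposite direction. The median ratio of the acetate to the glucose log2 fold change in them was 17.2% (quartiles 4.79% and 31.6%), or 12.2% to 17.3% with the 1 mM libraries divided between the comparisons. Of these genes 4200 (92.4%) still differed between 10 mM glucose and acetate.

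Both comparisons share the 1 mM libraries, which makes fold changes correlate without any effect. Across genes Pearson's r was 0.532, and 20 simulated sets with unchanged groups gave a mean of 0.51 and the same sign in a mean of 66.8% of all genes, called or not, but a covariance of 0.00961 against 0.112 found. With the 1 mM libraries divided between the comparisons in the 6 possible ways, 33 to 571 genes were called in the same direction and 3 to 45 in the opposite one, and the covariance was 0.09 to 0.11. The count of 1562 became 1021 without 1 mM replicate 1, 1006 without 1 mM replicate 4 and 941 without acetate replicate 4.

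**Figure D4:**
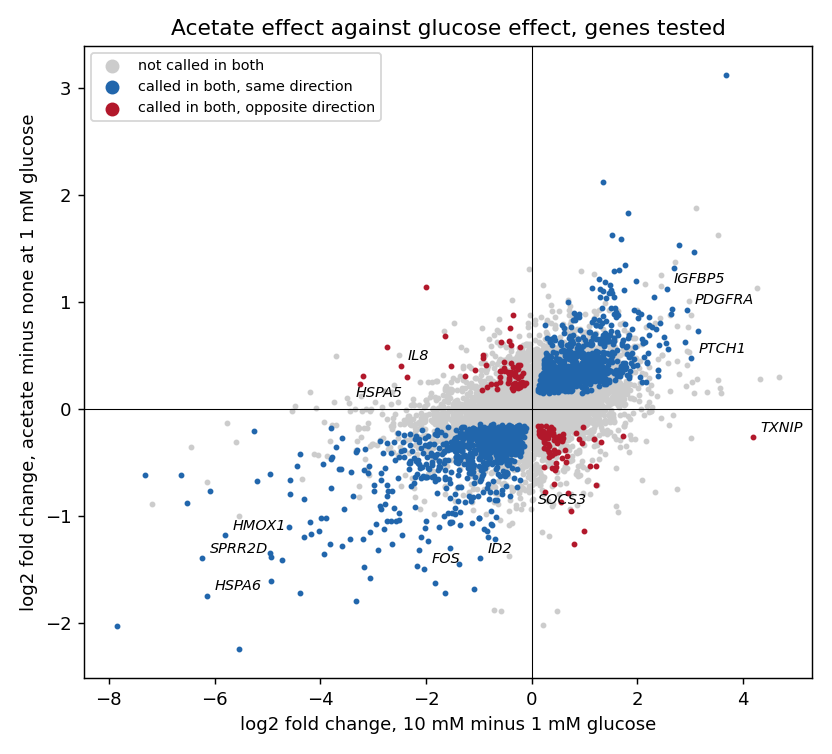
Log2 fold change with acetate (vertical) against log2 fold change with 10 mM glucose (horizontal), both relative to 1 mM glucose, with 1 point per tested gene. Blue points are the 1562 genes called in both comparisons in the same direction and red points the 146 called in opposite directions.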

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

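The tests of scaling for the ribosomal protein genes and of a swap between 1 mM replicate 2 and acetate replicate 1 were chosen only after the results were seen, and so were the settings that remove the trend over transcript length and GC content.

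Single libraries lay apart from the other 3 of their group, by a gap above Dixon's critical share of the group's range for 4 samples, in 13 of 228 tests of 76 named genes and 4 of 30 tests of library measures. Chance gives about 1 in 20. In acetate replicate 1, PTCH1 was at 16.3 CPM (mean of the other 3, 25.3) and ACLY at 184 CPM (218). In acetate replicate 2 MYCN was at 5.23 CPM (3.88), and in acetate replicate 4 DUSP1 was at 23.0 CPM (27.3) and IL8 at 225 CPM (265). At 1 mM glucose, SESN2 was at 268 CPM in replicate 2 (288), and SERPINA5 at 12.99 CPM (10.1) and NAGK at 42.8 CPM (36.9) in replicate 3. At 10 mM glucose, KLHDC7B was at 0.155 CPM (0.182) and GDF15 at 7.93 CPM (9.64) in replicate 1, and in replicate 3 PPP1R15A was at 64.1 CPM (60.1), SLC2A1 at 210.05 CPM (195) and CRELD2 at 70.4 CPM (65.4). Among library measures these were the total count of 10 mM replicate 1, 24.4 M (26.0 M), the share of counts in HSPA5 of 10 mM replicate 3, 0.123% (0.126%), principal component 3 of acetate replicate 1, −20.5 (−10.3), and the TMM factor of 1 mM replicate 1, 0.952 (0.962).

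Genes such as PDGFRA and HMOX1 changed with acetate in the direction in which they changed with glucose, as did 91.5% of the genes called in both comparisons. The shared 1 mM libraries are argued against as the whole cause, because at least 91.7% changed the same way in each of the 6 ways of dividing these libraries between the comparisons. A trend over length and GC content is argued against as well, since 85.9% (2923 genes) changed the same way after it was removed. That acetate stands in for part of the supply of glucose is a candidate explanation given by the design, and it stays open. No other effect of the added acetate was tested.

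The 24 ribosomal protein genes, RPL3, RPL4 and RPL5 among them, were lower at 10 mM glucose by a median of −0.70. Their transcripts are short, at a median length percentile of 8.42, and after the length and GC trend was removed the median was −0.48 (quartiles −0.61 and −0.44) with 23 of 24 called by edgeR, so the trend may account for part of the decrease and is argued against as the whole. Scaling of the libraries is argued against as the whole cause, because it moves all genes alike, while of 10000 random lists matched for length, GC content and level, with a median of −0.31, only 6 were as low. This count is no probability, because the random genes were drawn independently and the ribosomal list had an estimated correlation of 0.896. Ribosomal protein genes outside the 24 could also be drawn. Reads shared with pseudogenes and a response to glucose stay open and were not tested.

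The libraries 1 mM replicate 3 and acetate replicate 1 deviated from their groups together, and another division of the 8 libraries, with 1 mM replicates 1, 3 and 4 and acetate replicate 1 against the rest, called 3602 genes where the real one called 1980. Exchanged labels of 1 mM replicate 3 and acetate replicate 1 are argued against, because over the 50 genes that best separate the other 6 libraries the farther lay at 0.192 and the nearer at 0.121 of the way from its own group to the other. Exchanged labels of 1 mM replicate 2 and acetate replicate 1 are argued against likewise, at 0.206 and 0.197 for these libraries. Removing the length and GC trend took the other division to 1564 genes and the real one to 3988, so this trend may be the source of the larger count, and it took the correlation of the deviations from 0.591 only to 0.463, so most of that correlation stays open. RNA quality and library batch could each give such a trend, and neither is given in the sources used here.

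Chance was tested by dividing the 8 libraries of each comparison into groups of 4 in all 35 ways. The lowest result this test can give is 1 of 35, the real division itself. It concerns only how these libraries are divided. Since the replicates are not said to be separate cultures, it cannot exclude a chance difference between cultures. For the genes called for glucose a chance division is argued against, with 1 of 35 divisions as large (9725 against a highest other of 0 by edgeR, or 10118 against 3009 at an unadjusted p under 0.05). The other divisions mix the conditions, which puts the real difference into the spread, so their edgeR counts of 0 add little. For the remaining difference a chance division is argued against with the same limit, at 1 of 35 (9049 against a highest other of 0 by edgeR, or 9522 against 1889 at an unadjusted p under 0.05). For the genes called for acetate it cannot, with 2 of 35 (1980 against 3602), which points to a structure among the samples, and after the length and GC trend was removed it can, with 1 of 35 (3988 against 1564). For the number of gene lists called for glucose the count of divisions, 7 of 35 (13 lists against a highest other of 13), is no measure of chance. Divisions that keep 3 libraries of a condition together carry part of the real contrast and called 10 to 13 lists, and those with 2 libraries of each condition called 0 to 3 by camera. For the lists called for acetate chance cannot be excluded, with 2 of 35 (13 against 13). For those of the remaining difference 1 of 35 was as large (17 against 14), the lowest result the test can give.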

How the results depend on the processing

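The alternatives chosen after the data were seen are those with the other transcripts, without the pair of libraries set apart by transcript length, with the length and GC trend removed, and library totals or DESeq2 size factors for lists and library totals for the overlap. No result reversed. The count of genes called for glucose was 7988 to 10524 and that for the remaining difference 7490 to 10008 over the alternatives other than a 1.5-fold minimum, which gave 4547, 380 (acetate) and 3672 by its construction. For acetate, edgeR called 1056 genes with only the 8 libraries compared, 3728 without the pair of libraries set apart, 3988 with the trend removed and 3623 with the replicate block as well. Leaving out 1 library gave 9087 to 9791 genes for glucose, 1196 to 2956 for acetate (1196 without acetate replicate 4, 2956 without acetate replicate 1) and 8421 to 8900 for the remaining difference. Of the genes changed the same way by glucose and acetate there were 941 to 2319 with 1 library left out, 2940 without the pair, 2923 with the trend removed, 2702 with the block as well, and 258, 408, 33, 571, 248 and 497 with the controls divided, where fewer libraries enter each comparison. Over these settings 85.9% to 95.1% of genes called in both changed the same way. Lists called were 13 to 14 for glucose, 10 to 14 for acetate and 14 to 17 for the remaining difference with 1 library left out, 1, 1 and 2 with an estimated correlation, and 27, 13 and 26 by fry, which tests a list against no change and not against other genes. For the ribosomal genes with acetate fry gave adjusted p = 0.453. With the other settings they were 13 to 16, 9 (library totals) to 13 and 14 to 17. For acetate, library totals ended the camera calls of ER (adjusted p = 0.0554), FOXO (0.0559), cholesterol (0.0559) and inflammatory genes (0.0713). Leaving out the pair ended those of cholesterol and inflammatory genes (0.12 each). Removing the trend ended those of cholesterol and ribosomal genes (0.0874 each, or 0.0888 and 0.0754 with the block), and with the block also p53 genes (0.0547). For the remaining difference autophagy was lost with library totals (0.0628), without the pair (0.0639) and with the trend removed (0.0544, or 0.052 with the block). Acetyl-CoA, cholesterol (0.0628 each) and extracellular matrix genes (0.139) were lost with marked transcripts alone. Over its alternatives camera gave adjusted p = 0.0029 to 0.376 for ER, 0.0281 to 0.255 for cholesterol, 0.0112 to 0.454 for inflammatory and 1.1e-04 to 0.762 for ribosomal genes for acetate, and 0.0188 to 0.482 for autophagy and 0.029 to 0.175 for acetyl-CoA genes for the remaining difference. The replicate block ended the camera calls of p53 (adjusted p = 0.0576, over the camera alternatives 0.0241 to 0.255) and FOXO genes (0.0606, 0.0156 to 0.365) for acetate, and of hexosamine (0.0531, 0.029 to 0.419), cholesterol (0.0531, 0.0287 to 0.23) and extracellular matrix genes (0.0536, 0.0072 to 0.418) for the remaining difference, with the highest of these values at an estimated correlation. DESeq2 called 9784, 2302 and 9020 genes, limma-voom 9726, 1947 and 9049, and the replicate block 9613, 1780 and 8899. Named genes such as HSPA5 and TXNIP kept their direction and side of the threshold in each of 352 values with 1 library left out and 566 others for glucose, and 304 and 489 for the remaining difference. For acetate 21 calls were lost and 2 gained with 1 library left out, against 337 values unchanged in this, and 11 lost and 4 gained in the others, against 567. TXNIP had edgeR adjusted p from 0.0107 (trend removed, with the block) to 0.155 (only the 8 libraries), and MSH6 from 0.002 to 0.0564 (trend removed, with the block). Except where the number of libraries or the size of the minimum explains a change, the cause was not tested. Depth was not varied. At this depth and replication 52.8% of the smallest simulated changes and 97.2% of those of 1.5-fold were recovered. That holds for genes of at least 5 CPM in sets simulated without a length and GC trend. A pseudocount on normalized values was not varied because the values are counts.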

Other observations

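These 4 gene lists were chosen only after the fold changes had been seen, so their camera p-values, which are not adjusted, cannot count as evidence.

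Heat shock genes were lower with acetate in 13 of 16 (median −0.58, camera p-value of 1.6e-15, or 0.0242 with an estimated correlation), among them DNAJB1 (−1.18), BAG3 (−1.05), HSPH1 (−0.97) and HSP90AA1 (−0.48). At 10 mM against 1 mM glucose 11 were lower (median −0.77, 1.2e-04, or 0.226), HSPA1A by −4.93, and at 10 mM glucose against acetate 4 were higher and 9 lower (median −0.43, 0.0832, or 0.571).

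Hedgehog pathway genes were higher at 10 mM glucose in 9 of 11 and lower in 1 (median 1.07, camera p-value of 3.6e-04, or 0.0566 with an estimated correlation), with PTCH1 at 3.02, GLI1 at 1.90, GLI3 at 1.52 and CDON at −0.66. With acetate 3 were higher, PTCH1, GLI2 and SMO (median 0.22, 6.3e-04, or 0.0656), and against acetate 8 were higher and 1 lower at 10 mM (median 0.81, 9.6e-04, or 0.0737). Oligodendrocyte progenitor and proneural genes were higher at 10 mM glucose in 8 of 10 and lower in 2 (median 0.99, camera p-value of 0.0053, or 0.0172), with SOX8 at 2.22, OLIG1 at 2.47, OLIG2 at −1.555 and BCAN at −1.16. OLIG1 lay near the floor, at a mean of 0.149 CPM at 1 mM and 0.86 CPM at 10 mM glucose. With acetate 2 were higher, PDGFRA and SOX2, and OLIG2 lower (median 0.07, 0.346, or 0.351), and against acetate 8 were higher and 2 lower (median 0.94, 0.003, or 0.0127).

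N-glycosylation genes were lower at 10 mM glucose in 17 of 22 and higher in 2 (median −0.51, camera p-value of 6.7e-05, or 0.101 with an estimated correlation), with ALG12 at −1.10, RPN1 at −0.90 and STT3A at −0.74. With acetate 1 was higher, ALG6, and 2 lower, DHDDS and RPN1 (median −0.09, 0.0191, or 0.311), and against acetate 15 were lower at 10 mM (median −0.40, 1.3e-04, or 0.114).

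Some genes were called for acetate and not for glucose, 272 in all, or moved in opposite directions. SOCS3 changed by −0.94 with acetate and had −0.01 for glucose, and DNAJA1, HSPA8 and INSIG1 changed by −0.65, −0.51 and −0.51. KRT80 rose by 0.57 with acetate and fell by 2.73 with glucose on the log2 scale, and BIRC3 rose by 0.40 and fell by 1.53. SNAI1 fell by 0.77 and SNAI2 by 0.44 with acetate, while glucose raised them by 0.25 and 0.37.

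Fold changes of the genes were weakly related to transcript length, with a Spearman correlation of 0.214 for glucose, 0.223 for acetate and 0.168 for the remaining difference. Libraries with the same replicate number in different conditions had deviations correlated from −0.365 to 0.27, above 0.1 in 3 of 12 pairs, so the numbers were not taken to pair the samples.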
